A study of Homo sapiens with 8 samples.

How the data were processed

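RNA was measured by sequencing of polyA RNA in neural stem cells derived from the human embryonic stem cell line H9. The 8 libraries fall into 4 conditions of 2 libraries each, per the labels. The control line carried empty and scrambled vectors, 1hit expressed mutant IDH1 (R132H), 2hit added an shRNA against p53 and 3hit added an shRNA against ATRX as well. Libraries were made with an Illumina mRNA kit from column-purified RNA, per the labels' protocols. Nothing in the labels says whether the 2 libraries of a condition came from separate cultures, so the authors' p-values may measure technical spread.

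The deposited gene table gives FPKM (fragments per kilobase of gene model, scaled to the mapped fragments) as 1 value per condition, with a lower and an upper limit, per the file headers. The layout is that of Cuffdiff output, and the level of those limits is not stated. Reads were placed on hg19, per the submitters' processing notes. The aligner, its version and the scaling between libraries are not given in the sources used here. A second deposited table holds the authors' p-value and q-value for each of the 6 pairs of conditions. The authors' q-values equalled a Benjamini-Hochberg adjustment over all 117678 completed tests of the 6 pairs, with a largest difference of 5.29e-07. The smallest p-value in that deposited table, 5e-05, was shared by 6834 tests and gave its smallest q-value, 0.000861. It is the smallest value that the authors' test gave. A deposited list of k-means clusters assigns 2577 rows to 15 clusters, and the rule by which the authors chose those rows is not given in the sources used here.

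Values per library were not used here, so no mean, SD or test across replicates was computed. The design fixed for this case before the data were examined was followed instead of a limma fit. Log2 ratios were computed as log2((FPKM + 1)/(FPKM + 1)) from the deposited FPKM, which understates the change of low genes. A gene was called changed where the authors' deposited q-value was under 0.05, their test was marked as completed and the mean FPKM over the 4 conditions was at least 1. Total counts are not given in the sources used here, so sequencing depth is unknown. The deposited limits are the only measure of error for each value. Their median width to either side was 55.1% of the value, over 11889 rows with an FPKM of at least 1 in every condition.

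Of 63451 rows, 4947 carried no gene name and were left out. The remaining 58504 rows held 49361 names, each counted once at its row of highest mean FPKM. The minimum of 1 FPKM kept 14040 rows, of which 1969 join several names. Such a row is written here with a slash between genes, without clone-based, antisense and small RNA names where another name stands beside them. In 154 of the 14040 rows an FPKM lay outside its own deposited limits by more than 1%, and these are uncertain. Because strand handling is not given in the sources used here, antisense and overlapping genes cannot be separated. In the file, 25 names had been turned into dates by a spreadsheet.

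The rule for named genes was fixed before the data were examined. The rule covered the altered genes and SOX2 in every condition, then the 8 largest rises and 8 largest falls per comparison among called genes whose deposited limits did not overlap. For libraries that do not overlap, the rule's wording, limits were substituted. Genes on chromosome Y and XIST were left out of the naming, a step added after the rule was fixed. For each gene list with at least 3 called members, up to 4 members with the smallest q-values were named, and likewise for the Notch, p53, neural stem, neuronal and astrocyte lists. The 29 gene lists, 535 symbols in all, were also fixed beforehand. Some genes that the rule covers are not reported here. Older symbols were matched through the synonyms of a reference gene table for GRCh38, used for names only.

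For each list, the median log2 ratio was set against 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these libraries and is not a p-value. Counts of members were also taken with q-values adjusted over the list alone. The code was tested on simulated data for 1hit against control, with 14040 rows and independent noise in each row. A list of 20 rows shifted by 0.5 on the log2 scale reached the 100th percentile. Of 200 unchanged lists of 20 rows, 5.5% lay outside the central 95% of random lists. The simulated noise was smaller than the spread of the real log2 ratios, whose median absolute value was 0.39 in 1hit vs control. The simulation thus checks the code and does not measure the power to find a shift in these data. Overlaps of calls between comparisons that share a condition were set against 100 simulated sets of unchanged conditions, with noise drawn from the deposited limits read as 95% limits.

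The alternatives tried were a pseudocount of 0.1 or 5, no filter, a mean FPKM of at least 5, median centring, quantile normalization, an absolute log2 ratio of at least 1 and a q-value under 0.01. Chosen after seeing the data were a correction for GC content and length in 10 by 10 bins, and counts without joined rows or without rows outside their own limits. GC and length came from the longest GENCODE 29 transcript of each symbol, found for 89.4% of the 14040 rows. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.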

Results

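The series profiled polyA RNA from neural stem cells derived from H9 human embryonic stem cells. Its 4 lines model the stepwise alterations of a low-grade astrocytoma: a vector control, mutant IDH1 alone (1hit), mutant IDH1 with p53 knockdown (2hit) and mutant IDH1 with p53 and ATRX knockdown (3hit). There were 2 libraries per condition, and 1 deposited FPKM per condition with its limits, so each value below is the authors' value. Ranges in brackets are the deposited limits. In every comparison below, an effect of an alteration cannot be told apart from other differences between the lines. Sequencing depth is unknown, because total counts are not given in the sources used here.

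ATRX and IDH1 were read first. ATRX (X:76759410-77041702, hg19, the interval of its row) measured 13.9 FPKM in control, 14.3 in 1hit, 22.2 in 2hit and 9.07 in 3hit. Its log2 ratio of 3hit to 2hit, -1.20, did not pass the threshold (q = 0.150 in the authors' deposited table), nor did that of 3hit to control, -0.56 (q = 0.562 in the same deposited table of the authors). IDH1 (2:209100951-209130798) measured 132.3 FPKM in control (85.3 to 179), 80.9 in 1hit (51.6 to 110), 160 in 2hit and 101 in 3hit, so no line labelled as expressing mutant IDH1 had a called rise of the gene over control. The rows do not separate mutant from normal transcript. SOX2, a transcription factor of neural stem cells (3:180701497-181554668, an interval wider than the gene), stood at 46.1 FPKM in control, 6.31 in 1hit, 96.8 in 2hit and 23.7 in 3hit. The fall in 1hit (log2 ratio -2.69) and the rise in 2hit (1.05) were called, and the 3hit value was not (q = 0.0678 against control in the authors' deposited table).

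**Figure D1:**
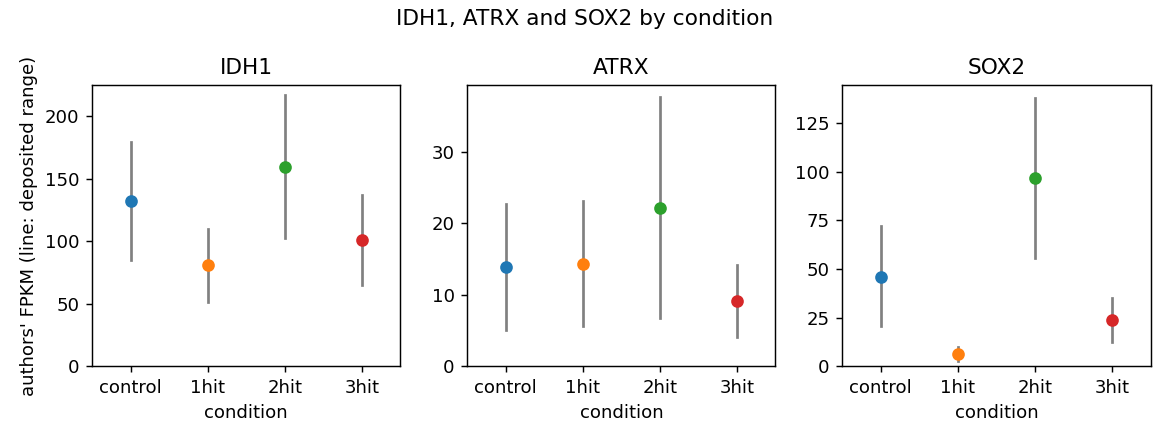
Authors' FPKM of IDH1, ATRX and SOX2 (y axis, from 0) in the 4 conditions (x axis), with points for the deposited value and lines for its deposited limits. SOX2 is lowest in 1hit at 6.31 FPKM and highest in 2hit at 96.8, and the ATRX ranges overlap in every condition.

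The comparison of 1hit with control asked what mutant IDH1 alone did to the neural stem cells. In 1hit, the neural stem cell and neuronal lists were lower and the mesenchymal and fibroblast list higher. Of 23 measured neural stem cell genes 12 fell and 1 rose, with a median log2 ratio of -1.61, below all 10000 random lists. FABP7, a fatty acid binding protein of radial glia, fell from 283 FPKM (181 to 385) to 4.17 (1.75 to 6.60). SOX1 fell from 20.2 to 0.422 and the RNA-binding protein gene MSI1 from 36.7 to 2.88. Of 17 neuronal genes 11 fell and 2 rose (median -1.35, also below all random lists). The neurofilament gene NEFM fell from 387 FPKM (198 to 576) to 3.39 (1.05 to 5.93), NEFL from 87.5 to 5.05 and the GABA synthesis gene GAD1 from 6.94 to 0.433, while RBFOX3 rose from 0.305 to 10.6. Adjusted over the list alone, 13 stem cell genes fell and 1 rose, and 13 neuronal genes fell and 2 rose.

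Mesenchymal and fibroblast genes moved the other way in 1hit: 14 of 16 rose and none fell, with a median log2 ratio of 2.35, above all random lists. COL1A1 rose from 67.3 to 2420 FPKM, COL3A1 from 26.7 (16.1 to 37.3) to 1873 (697 to 3052), COL5A1 from 5.77 to 236 and the surface glycoprotein gene THY1 from 11.5 to 259. The largest rise of all was in ALDH1A2, a retinoic acid synthesis enzyme, from 0.919 FPKM (0.563 to 2.84) to 1144 (598 to 1690). It was followed by the imprinted gene DLK1 (1.70 to 762), CD34 (0.495 to 311), PLAC9 (1.53 to 270), PRDM8 (0.122 to 100.5), the matrix gene SMOC2 (0.0945 to 89.2) and the transcription factor EBF2 (0.638 to 124). The largest falls, beside NEFM and FABP7, were in LYPD1 (94.3 to 0.107), the receptor phosphatase gene PTPRZ1 (95.8 to 0.237), AC018730.1 (156 to 2.43), GAD2 (48.2 to 0.213), the chemokine receptor gene CXCR4 (35.8 to 0.0868) and C1QL4 (133 to 3.10).

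Mitotic genes fell with them: 14 of 21 G2 and M phase genes were lower in 1hit and none higher (median -0.96, below all random lists). CDC20 fell from 80.0 to 26.4 FPKM, BIRC5 from 66.0 to 25.6, CCNB2 from 92.9 to 37.4 and UBE2C from 226 to 103, and 18 were lower when adjusted over the list alone. Of 20 G1 and S phase genes 1 fell, and none adjusted over the list alone, at a median of -0.55 below all random lists. Among 16 integrated stress response genes 10 rose and none fell (median 1.18). They included TRIB3 (6.28 to 41.3), the asparagine synthetase gene ASNS (34.4 to 176), ATF3 (1.27 to 5.49) and PSAT1 (66.9 to 179). Of 19 hypoxia response genes 6 rose and none fell, EGLN3 from 2.27 to 59.4, NDRG1 from 2.02 to 23.5, P4HA2 from 3.60 to 29.3 and BHLHE40 from 7.09 to 34.8. The list's median of 0.28 lay at the 93.9th percentile, and after correction for GC content and length it was 0.433 at the 99.4th.

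Developmental regulators were split in 1hit. HOXD1 (0.201 to 25.5), the joined row HOXD3/HOXD4 (0.0513 to 21.4) and HOXD8 (0.0190 to 15.9) rose, while the joined HOXB2/HOXB3/HOXB4/HOXB6 row fell from 75.9 to 17.8, out of 6 measured HOX rows. Of 5 neural crest genes 3 rose and 1 fell: NGFR (8.51 to 91.0), SNAI1 (1.11 to 11.4) and ETS1 (14.3 to 44.2) against TFAP2B (76.5 to 2.04). Of 13 Notch pathway genes 5 fell and 2 rose. LFNG rose from 14.3 to 121 and NOTCH2 from 14.5 to 47.4, whereas DLL3 fell from 10.4 to 1.63 and NOTCH1 from 30.7 to 6.60. The list's median of -0.36 at the 1.98th percentile moved inside the central 95% with a pseudocount of 0.1 or 5. All 4 called genes of the 14 in the Wnt list fell, namely the secreted inhibitor SFRP1 (23.6 to 0.560), LGR5 (2.20 to 0.0509), NKD1 (2.12 to 0.0758) and DKK1 (5.99 to 1.31). Of 14 DNA methylation genes 3 fell and none rose, DNMT3B from 9.80 to 1.58, UHRF1 from 29.1 to 8.69 and TET3 from 13.9 to 7.12, while TET1 measured 3.34 and 1.85.

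Astrocyte genes went both ways in 1hit, 6 higher and 4 lower of 15. S100B fell from 164 to 6.77 FPKM, while CLU rose from 79.6 to 558, TNC from 89.2 to 548 and CD44 from 17.5 to 87.4. Of 30 p53 targets 5 rose and none fell, among them PHLDA3 (18.2 to 89.6), GDF15 (1.25 to 6.36), GADD45A (15.5 to 46.4) and BTG2 (5.47 to 13). The median log2 ratio of the p53 list was 0.13, at the 79.4th percentile, so as a list it did not stand out from random lists. Immediate early genes rose in 5 cases and fell in 1 of 13, with NR4A1 at 10.6 and 60.2, EGR2 at 7.97 and 27.1 and DUSP1 at 5.93 and 20.4. Of 13 imprinted genes 4 rose and 3 fell. The row joining IGF2, INS and INS-IGF2 rose from 186 to 4440, PLAGL1 from 7.22 to 32.7 and IGF2R from 20.5 to 72.1. Of 20 cholesterol synthesis genes 4 rose, including INSIG1 (60.9 to 147), MSMO1 (108 to 191) and DHCR7 (49.3 to 89.5).

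In total 2350 of 13813 genes tested were called between 1hit and control, 1337 higher and 1013 lower in 1hit. Ribosomal protein genes, with no member called of 27, had a median of 0.36 that turned to -0.03 after quantile normalization. Because each condition has 1 deposited value, agreement between its libraries was not examined here.

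**Figure D2:**
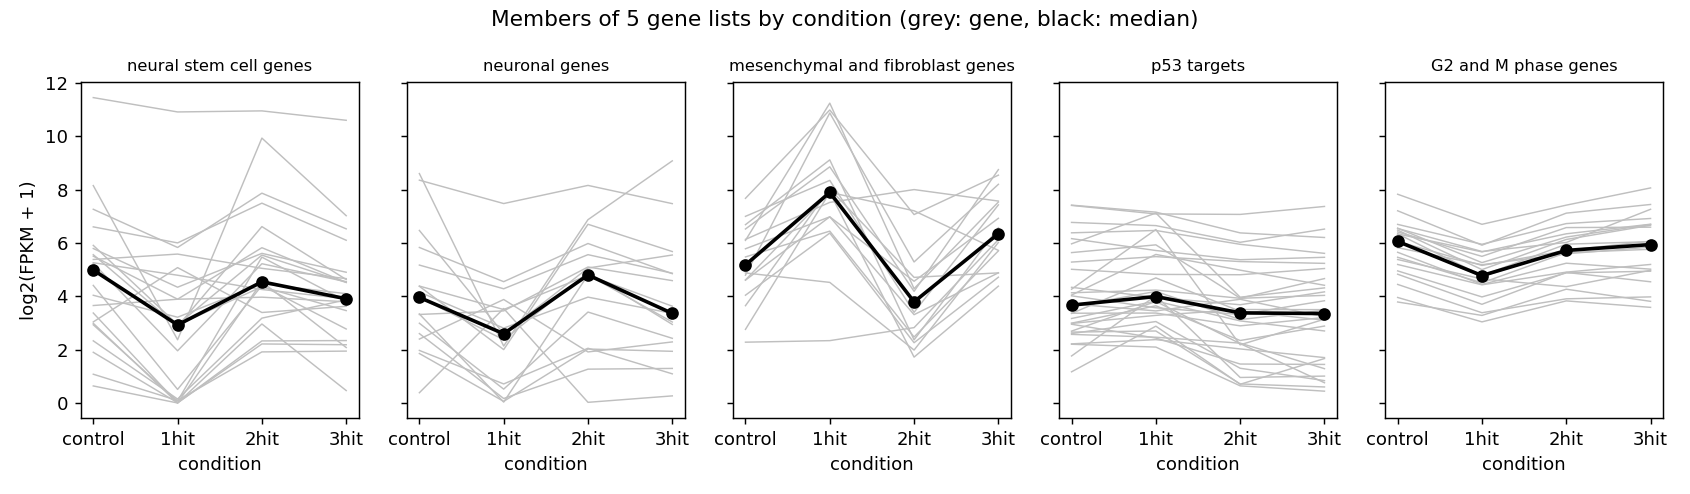
Each grey line is a measured gene of 1 list, as log2(FPKM + 1) (y axis) across the 4 conditions (x axis), and the black line joins the medians. In 1hit, 12 of 23 neural stem and 11 of 17 neuronal genes were called lower than control and 14 of 16 mesenchymal genes higher, and in 2hit 10 of those 16 were lower.

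The comparison of 2hit with control asked what mutant IDH1 did together with p53 knockdown. As lists, the p53 targets and the mesenchymal genes were lower and the neural stem cell genes higher. Of 30 p53 targets 7 fell and 1 rose, with a median log2 ratio of -0.48, below all random lists. PHLDA3 fell from 18.2 to 3.53 FPKM, the receptor gene EDA2R from 5.31 to 0.640, the kinase gene PLK2 from 48.8 to 14.2 and SPATA18 from 3.60 to 0.560. Of 16 mesenchymal genes 10 fell and 2 rose (median -1.26, below all random lists). POSTN fell from 102 (62.0 to 142) to 4.16 (1.43 to 6.89), DCN from 127 to 9.54, PRRX1 from 43.5 to 4.55 and TWIST1 from 28.3 to 2.95. Of 23 neural stem cell genes 7 rose and 2 fell (median 0.32, 99.3rd percentile), among them SOX3 (6.62 to 43.2), HES5 (0.556 to 6.79), FABP7 (283 to 975) and SOX21 (6.92 to 22.3). Adjusted over the list alone, the counts of the p53 and stem cell lists were the same, and 3 mesenchymal genes rose and 10 fell.

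The largest falls in 2hit, beside POSTN, were in GAD2 (48.2 to 0.0589), the transcription cofactor gene LMO2 (162 to 2.87), the matrix gene MGP (203 to 4.0), TRIL (77.1 to 1.72), EMILIN1 (70.1 to 2.06), the acetylcholine receptor gene CHRNA1 (48.2 to 1.19) and C1QL4 (133 to 6.09). The largest rises were in TRIM48 (1.18 to 56.4), EPAS1, which encodes a hypoxia-inducible factor subunit (0.171 to 24.9), TFPI2 (1.97 to 57.6), the calcium channel subunit gene CACNG5 (0.619 to 28.1), AHNAK2 (1.25 to 30.1), the VEGF receptor gene KDR (1.18 to 26.8), PODXL (2.58 to 42.4) and APLN (0.487 to 15.0). KDR was the 1 measured member of the endoderm and mesoderm list.

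Neuronal genes went both ways in 2hit, 3 higher and 3 lower of 17. GAP43 rose from 19.7 to 103, INA from 8.98 to 33.2 and STMN2 from 9.10 to 26.8, while NEFM fell from 387 to 116. Astrocyte genes were also split 3 to 3 of 15, with CD44 (17.5 to 97.9) and CLU (79.6 to 421) higher and ID3 (454 to 115) and APOE (27.1 to 8.41) lower. The list's median of -0.24 at the 1.03rd percentile moved inside the central 95% with a pseudocount of 5 and after quantile normalization. Of 16 integrated stress response genes 5 rose and none fell (median 0.58, above all random lists), including ATF3 (1.27 to 9.58), CHAC1 (1.66 to 8.0), ASNS (34.4 to 116) and TRIB3 (6.28 to 12.8). All 3 called Notch genes of 13 rose, namely HES5, JAG1 (17.8 to 36.2) and DLL1 (2.61 to 5.32). Among 14 Wnt genes 3 rose and 4 fell, with WNT7A (0.0679 to 3.81) and SFRP2 (5.46 to 23.5) higher and FZD8 (30.1 to 2.16) and LEF1 (23.9 to 5.89) lower. The neural crest genes NGFR (8.51 to 0.763), PAX3 (10.002 to 3.01) and TFAP2B (76.5 to 30.3) fell. Of 13 immediate early genes 3 rose, ATF3, DUSP1 (5.93 to 12.0) and MYC (4.89 to 13.5), and EGR2 (7.97 to 2.26) fell. The glucose transporter gene SLC2A1 (17.9 to 94.7) and ADM (19.8 to 40.4) rose from the hypoxia list and NDRG1 (2.02 to 0.718) fell. Of 8 histone genes 3 rose and none fell, HIST1H2AC (1.03 to 4.43), HIST1H2BD (2.76 to 9.35) and HIST2H2BE (3.79 to 10.1), although a polyA library records few transcripts of this class. From the pluripotency list, DPPA4 (13 to 61.6) and LIN28A (1.61 to 4.61) rose and L1TD1 (25.7 to 0.605) fell. Of 13 imprinted genes 2 rose, DLK1 (1.70 to 27.5) and PHLDA2 (12.7 to 54.0), and 3 fell, among them MEST (454 to 142) and MAGEL2 (13 to 3.96). In total 1145 of 13783 genes were called, 648 higher and 497 lower in 2hit.

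The comparison of 3hit with control asked what all 3 alterations did. As lists, the p53 targets were again lower, and the mesenchymal genes were higher, not lower. Of 30 p53 targets 9 fell and none rose (median -0.48, below all random lists). EDA2R fell from 5.31 to 0.516, BTG2 from 5.47 to 0.691, ZMAT3 from 5.07 to 0.787 and SPATA18 from 3.60 to 0.359. Of 16 mesenchymal genes 10 rose and none fell (median 1.14, above all random lists), with COL1A2 up from 3.85 (1.59 to 6.12) to 68.6 (31.4 to 106), COL3A1 from 26.7 to 293, COL6A3 from 90.9 to 429 and COL5A1 from 5.77 to 19.8. Of 23 neural stem cell genes 7 fell and 3 rose (median -0.73, below all random lists). SOX1 fell from 20.2 to 5.84, NOTCH1 from 30.7 to 10.02 and SOX9 from 37.3 to 14.0, while LIN28B rose from 4.03 to 13.6. Adjusted over the list alone, 14 stem cell genes fell and 3 rose, 11 mesenchymal genes rose and none fell, and the p53 counts were the same.

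Of 17 neuronal genes 7 fell and 2 rose in 3hit, with NEFL down from 87.5 to 45.7 against GAP43 (19.7 to 50.2) and INA (8.98 to 23). TNC (89.2 to 512) and FGFR3 (3.54 to 10.2) rose from the astrocyte list, and SLC1A3 (77.5 to 14.0) and S100B (164 to 31.1) fell, with 2 higher and 3 lower of 15. The largest falls of all were in the aldo-keto reductase gene AKR1C1 (21.8 to 0.0641), the linker histone gene H1F0 (271 to 13.3), C1QL4 (133 to 6.69), LMO2 (162 to 8.37), GAD2 (48.2 to 1.90), TM4SF1 (19.7 to 0.322), LYST (45.8 to 2.37) and FAM181B (17.2 to 0.321). The largest rises, beside COL1A2 and COL3A1, were in the homeobox genes BARX1 (1.03 to 31.0) and SHOX2 (0.126 to 10.004), EBF2 (0.638 to 23.3), AIF1 (0.435 to 19.1), FIGF (1.83 to 24.6), which encodes a VEGF family ligand, and RARRES2 (1.72 to 22.2).

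The 4 called stress response genes of 16 rose, ASNS (34.4 to 123), ATF3 (1.27 to 5.29), CHAC1 (1.66 to 5.33) and TRIB3 (6.28 to 14.4). Of 13 immediate early genes 3 fell, EGR2 (7.97 to 2.30), FOS (8.28 to 2.48) and JUN (69.9 to 31.4), and ATF3 rose. In the Notch list NOTCH1 and MAML2 (8.19 to 4.25) fell, while HES1 measured 40.6 and 24.3 and DLL1 2.61 and 1.53. SFRP1 (23.6 to 5.84), FZD8 (30.1 to 8.69) and WNT7B (7.65 to 2.12) fell in the Wnt list and LGR5 (2.20 to 7.37) rose. The neural crest genes SNAI1 (1.11 to 12.8) and NGFR (8.51 to 19.3) rose, and TFAP2B (76.5 to 8.73) and PAX3 (10.002 to 2.39) fell. Of 13 imprinted genes MAGEL2 (13 to 4.16), MEST (454 to 184) and NDN (102 to 58.0) fell and the IGF2 row (186 to 920) rose. HIST1H2AC (1.03 to 3.00), HIST1H2BD (2.76 to 8.07) and HIST1H2BK (15.0 to 30.5) rose. The 10 mitochondrially encoded genes had no called member and a median of 0.63 at the 99.9th percentile, which moved to 0.24 and inside the central 95% after quantile normalization. In total 1073 of 13807 genes were called, 496 higher and 577 lower in 3hit, and 680 at a q-value under 0.01.

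Against control, 184 genes were higher in both 2hit and 3hit and 228 lower in both. Independent lists of those sizes would share 21.7 and 20.9, and unchanged lines against the shared control, 2.94 and 3.02. The counts for unchanged lines are fixed largely by the cutoff on p. They cannot show how much a shared condition adds to the overlap among genes that changed. Part of the excess may come from the shared control. The covariance of the 2 sets of log2 ratios was 0.225 against 0.295 simulated, and their correlation 0.475 against 0.462. Noise alone gave more covariance in the simulation than the data held. The simulated noise may thus be too large, and no shared effect could be estimated or excluded. In 1hit and 3hit, 281 genes were higher in both and 309 lower in both, where independent lists would share 45.0 and 42.5, with a covariance of 0.307 against 0.294 simulated. In 1hit and 2hit, 191 were higher in both and 180 lower in both, where independent lists would share 57.5 and 36.7, with a covariance of 0.124 against 0.294. For these pairs too, the covariances cannot show whether an effect was shared.

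The comparison of 2hit with 1hit asked what p53 knockdown changed in cells with mutant IDH1. These are separate lines, and 1hit also differed from 3hit at 2239 called genes. The changes below may thus reflect the 1hit line itself and not p53 knockdown. As lists, neural stem cell and neuronal genes were higher in 2hit and mesenchymal genes lower. Of 23 neural stem cell genes 14 rose and 1 fell (median 2.04), and of 17 neuronal genes 13 rose and 2 fell (median 1.43), both above all random lists. FABP7 rose from 4.17 to 975 FPKM (440 to 1512), SOX2 from 6.31 to 96.8, SOX1 from 0.422 to 20.1, MSI1 from 2.88 to 36.3, NEFM from 3.39 to 116, GAP43 from 3.00 to 103 and GAD1 from 0.433 to 9.62, while RBFOX3 fell from 10.6 to 0.0169. Of 16 mesenchymal genes 13 fell and none rose (median -3.94, below all random lists), including COL1A1 from 2420 (1496 to 3347) to 18.5 (7.94 to 29.1), POSTN from 553 to 4.16, COL5A1 from 236 to 2.29 and COL3A1 from 1873 to 38.0. Of 30 p53 targets 11 fell and none rose (median -0.68, below all random lists), among them PHLDA3 (89.6 to 3.53), GDF15 (6.36 to 0.626), PLK2 (59.9 to 14.2) and EDA2R (5.49 to 0.640). Adjusted over the list alone, 14 mesenchymal genes fell, and the counts of the other 3 lists were the same.

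ALDH1A2 had the largest fall, from 1144 FPKM to 0.637, followed by MGP (962 to 4.0), PLAC9 (270 to 0.516), the proteoglycan gene BGN (1384 to 9.60), COL1A1, POSTN, IGFBP6 (148 to 0.638) and the IGF2 row (4440 to 51.1). The largest rises, beside FABP7, were in PTPRZ1 (0.237 to 208), the lipase gene LPL (0.366 to 162), LYPD1 (0.107 to 88.5), SPP1 (0.484 to 112), SCG2 (0.392 to 83.3), TRIM48 (listed at 0 in 1hit, 56.4 in 2hit) and the neural transcription factor POU3F2 (0.124 to 49.5). Of 21 G2 and M phase genes 5 rose, including BUB1 (12.0 to 28.7), CDC20 (26.4 to 61.0), HMMR (8.73 to 18.2) and CCNB1 (59.4 to 138), and adjusted over the list alone 13 rose. Of 14 Wnt genes 7 rose and 3 fell, with SFRP1 (0.560 to 17.6), DKK1 (1.31 to 17.2) and WNT7A (0 to 3.81) higher and FZD8 (18.6 to 2.16) lower. Of 13 Notch genes 5 rose and 2 fell, DLL3 from 1.63 to 10.5, DLL1 from 0.869 to 5.32 and HES5 from a listed 0 to 6.79 against LFNG (121 to 6.79). DNMT3B (1.58 to 19.8), TET1 (1.85 to 5.68) and UHRF1 (8.69 to 19.5) rose among 14 DNA methylation genes. EGLN3 (59.4 to 1.67), NDRG1 (23.5 to 0.718), P4HA2 (29.3 to 3.37) and BHLHE40 (34.8 to 5.30) were among 6 falls in the hypoxia list, which also had 4 rises of 19. The stress response genes TRIB3 (41.3 to 12.8), PSAT1 (179 to 70.4) and CEBPB (13 to 4.71) fell and DDIT4 (12.0 to 36.3) rose.

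Astrocyte genes were split 3 to 3 of 15, with S100B (6.77 to 133) and SLC1A3 (18.1 to 93.8) higher and NFIA (18.1 to 3.02) and TNC (548 to 118) lower, and with q-values adjusted over the list alone 3 rose and 7 fell. The list's median of -0.43 at the 1.74th percentile moved inside the central 95% with a pseudocount of 0.1 and after quantile normalization. NGFR (91.0 to 0.763), SNAI1 (11.4 to 2.15) and ETS1 (44.2 to 18.4) fell and TFAP2B (2.04 to 30.3) rose. EGR2 (27.1 to 2.26), NR4A1 (60.2 to 8.63) and EGR1 (60.7 to 29.1) fell and JUN (27.2 to 86.0) rose. In the pluripotency list LIN28A (0.0363 to 4.61) and DPPA4 (24.5 to 61.6) rose and POU5F1 (21.7 to 8.44) and L1TD1 (5.80 to 0.605) fell. INSIG1 (147 to 30.1), MSMO1 (191 to 106) and MVD (150 to 69.9) fell in the cholesterol list. PHLDA2 rose from 5.51 to 54.0, while DLK1 (762 to 27.5) and MEST (544 to 142) fell, in an imprinted list with 2 higher and 5 lower of 13. HIST1H2AC (1.28 to 4.43), HIST1H2BD (2.35 to 9.35), HIST1H1C (6.68 to 16.6) and HIST2H2BE (4.14 to 10.1) rose. Of 27 ribosomal protein genes 4 fell, RPL10 (1743 to 791), RPS18 (2286 to 1133), RPS12 (1871 to 1025) and RPL19 (1702 to 959), and adjusted over the list alone 8 fell. The list's median of -0.64 shrank to -0.07 after quantile normalization. In total 2364 of 13851 genes were called, 1162 higher and 1202 lower in 2hit.

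Of the genes higher in 1hit than in control, 872 were lower in 2hit than in 1hit, and of those lower in 1hit, 722 were higher in 2hit. Independent lists would share 117 and 82.8 genes, and unchanged lines sharing 1hit, 3.29 and 3.60. As above, the counts for unchanged lines are fixed largely by the cutoff on p. Part of this excess may come from the 1hit value that both ratios hold. The covariance of the ratios was -0.954 against -0.309 simulated, and their correlation -0.814 against -0.488. Both lie beyond what noise of the simulated size gave, which argues against such noise as the whole source. A departure particular to the 1hit line would give the same pattern and was not tested.

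The comparison of 3hit with 2hit asked what ATRX knockdown added. As lists, mesenchymal genes were higher in 3hit and neural stem cell genes lower. Of 16 mesenchymal genes 12 rose and 1 fell (median 2.79, above all random lists), with COL6A3 up from 17.2 (5.82 to 31.9) to 429 (146 to 731), POSTN from 4.16 to 93.9, TWIST1 from 2.95 to 63.9 and DCN from 9.54 to 171. Of 23 neural stem cell genes 10 fell and none rose (median -0.71, below all random lists), FABP7 from 975 to 129, SOX21 from 22.3 to 3.22, SOX2 from 96.8 to 23.7 and SOX3 from 43.2 to 13.1. Of 17 neuronal genes 4 fell, including NCAM1 (28.7 to 6.70), STMN2 (26.8 to 7.20) and GAP43 (103 to 50.2), and NEFM rose from 116 to 539. Adjusted over the list alone, 12 stem cell genes fell and 1 rose, 8 neuronal genes fell and 1 rose, and the mesenchymal counts were the same. Of 30 p53 targets BTG2 (3.68 to 0.691) and RRM2B (3.73 to 1.44) fell and GDF15 (0.626 to 2.17) rose. ATRX itself was not called in this comparison.

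The largest falls in 3hit were in CACNG5 (28.1 to 0.162), AHNAK2 (30.1 to 0.372), SCG2 (83.3 to 3.95), the ectonucleotidase gene NT5E (39.7 to 1.57), EPAS1 (24.9 to 0.980), TMEM158 (92.4 to 6.91), FRMD5 (14.2 to 0.451) and SYNDIG1 (10.9 to 0.146). The largest rises, beside COL6A3, POSTN and TWIST1, were in the S100A3/S100A4 row (7.21 to 182), the metalloprotease inhibitor gene TIMP3 (2.38 to 68.8), BGN (9.60 to 204), MGP (4.0 to 92.4) and the IGF2 row (51.1 to 920). Of 14 Wnt genes 3 rose and 4 fell, with LEF1 (5.89 to 34.4), LGR5 (1.29 to 7.37) and FZD8 (2.16 to 8.69) higher and WNT7A (3.81 to 0.517) lower. Of 13 Notch genes 5 fell and 2 rose, and JAG1 (36.2 to 12.7), DLL1 (5.32 to 1.53), HES5 (6.79 to 0.381) and MAML2 (8.51 to 4.25) were among the falls. Of 15 astrocyte genes 4 fell and 3 rose, among them CLU (421 to 61.1), SLC1A3 (93.8 to 14.0) and CD44 (97.9 to 20.5) lower and TNC (118 to 512) higher. NGFR (0.763 to 19.3) and SNAI1 (2.15 to 12.8) rose and TFAP2B (30.3 to 8.73) fell. SLC2A1 (94.7 to 26.4) and ADM (40.4 to 15.9) fell and NDRG1 (0.718 to 2.58) rose. JUN (86.0 to 31.4), FOS (7.49 to 2.48) and FOSL1 (15.5 to 1.81) fell. LIN28A (4.61 to 11.3), POU5F1 (8.44 to 18.0) and L1TD1 (0.605 to 6.29) rose in the pluripotency list. The imprinted genes PHLDA2 (54.0 to 6.88) and DLK1 (27.5 to 3.99) fell. In total 1237 of 13793 genes were called, 479 higher and 758 lower in 3hit, and 792 at a q-value under 0.01.

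**Figure D3:**
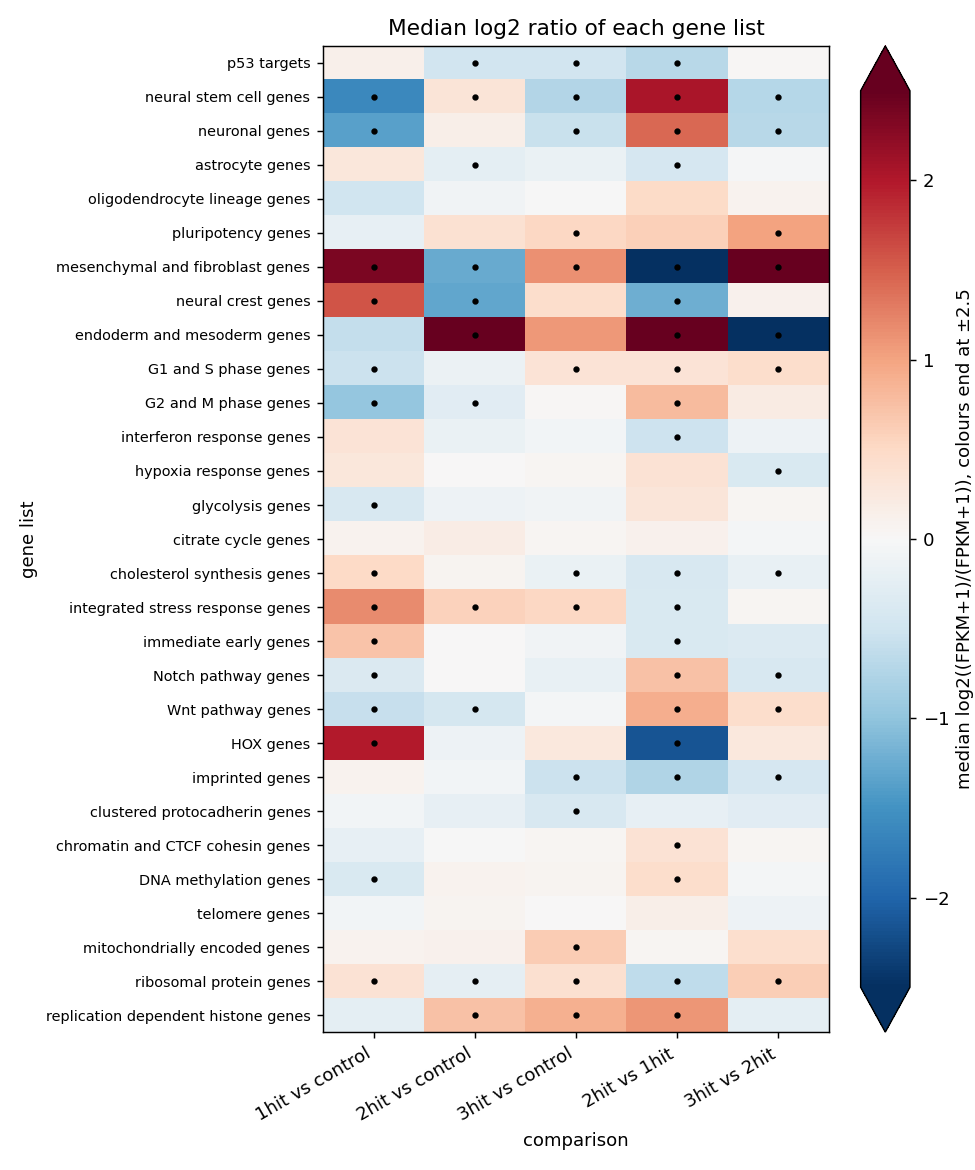
Colour gives the median log2 ratio of each of the 29 gene lists (rows) in each of the 5 comparisons (columns), red for higher in the first condition named, with the colour scale ending at ±2.5. A dot marks a median outside the central 95% of random lists, and the mesenchymal list runs from -3.94 (2hit vs 1hit) to 2.79 (3hit vs 2hit).

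Other lists held few called genes. Telomere genes had 1 called of 12 measured, higher in 2hit than in control, and the 7 clustered protocadherin rows had none in any of the 5 comparisons. Of 19 citrate cycle genes 1 was called, higher in 1hit than in control. Glycolysis genes, 17 in all, had 2 higher in 2hit than in 1hit, 1 higher in 3hit than in control and 1 lower in 3hit than in 2hit. Interferon response genes, with 12 measured, had at most 2 called in a comparison, and the 5 oligodendrocyte lineage genes likewise. Of 18 chromatin and cohesin genes 1 fell in 1hit against control and 1 rose in 2hit against 1hit. Over the 29 lists and 5 comparisons, 145 results in all, 39 medians lay below the central 95% of random lists and 33 above it. Lists of genes drawn at random would give 7.25 outside. Members of a real list can move together, lists share members and comparisons share conditions, so 7.25 is not a chance expectation here. The median and the mean of a list differed in sign in 18 results, among them glycolysis in 1hit against control (-0.40 and 0.10) and hypoxia in 2hit against 1hit (0.36 and -0.36).

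The authors' k-means clusters were chosen on these libraries and so are no independent evidence. Of their 2577 rows 383 had no gene name and 2178 were matched to a named row. Cluster 12, with 337 rows, had a median of 3.3 FPKM in 1hit and 0.1 in each other condition, and held COL1A1, COL3A1, COL5A1, THY1, DLK1, HOXD1 and HOXD8. Cluster 9, with 106 rows, had medians of 4.95 in control, 4.15 in 1hit, 0.75 in 2hit and 0.8 in 3hit, and held the p53 targets EDA2R, PLK2, SPATA18 and ZMAT3. Cluster 2, with 206 rows, was highest in 2hit (7.8) and lowest in 1hit (0.4), and held SOX1, SOX2, NES and MSI2. Cluster 13, with 100 rows, stood at 3.3 in 3hit and 0.4 elsewhere, and held COL1A2, TWIST1, LGR5 and LIN28A.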

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

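The tests of explanations in this part, with the correction for GC content and length, were chosen after the results had been seen. A signal outside the 5 main comparisons lay in the remaining pair of conditions. Between 3hit and 1hit the authors' deposited table called 2239 of 13819 genes, 957 higher and 1282 lower in 3hit. The mesenchymal list fell in 9 of 16 genes and rose in 2 (median log2 ratio -1.88), the neural stem list rose in 8 of 23 and fell in 3 (0.88), and the G2 and M phase list rose in 11 of 21 (0.97). NEFM stood at 539 FPKM in 3hit and 3.39 in 1hit, and ALDH1A2 at 5.02 and 1144.

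Rows without a gene name, left out of every comparison, held signal too. Of 593 such rows with a mean of at least 1 FPKM, 29 were called higher and 41 lower in 1hit than in control, leaving out the 32 with an FPKM outside its own limits. The largest rise was at 7:15643534-15645168 (hg19), from 0.483 FPKM in control (0.131 to 0.815) to 17.5 in 1hit (8.10 to 24.6), with 0.0642 in 2hit and 3.73 in 3hit.

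In 1hit, neural genes were lower than in control and mesenchymal genes higher. A minority of other cells in the culture would leave most of each neural transcript, but the median 1hit to control ratio over 40 neural stem and neuronal genes was 0.217 (bootstrap 95% interval 0.0608 to 0.383). That ratio restates the fall of those lists given above, and its interval covers the spread between genes, not between cultures. An exchange of both libraries with those of 2hit or 3hit would leave the p53 targets lower in 1hit, but their list was lower in 2hit and 3hit than in 1hit (medians -0.68 and -0.90, both below all random lists), which argues against it. An effect of mutant IDH1 common to all lines that carry it would lower the neural stem list in 2hit too. In 2hit against control that list lay at the 99.3rd percentile. This cannot decide the question, because 2hit also carries p53 knockdown and is a separate line. In 3hit, however, that list lay below all random lists (median -0.73) and the mesenchymal list above them (1.14), as in 1hit. An exchange with control libraries cannot be told apart, because the IDH1 ratio of 1hit to control was 0.611 with overlapping limits; a drift of the 1hit culture, a replacement of its cells, or an effect of mutant IDH1 that is absent from 2hit may also account for the pattern, and none of these was tested.

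In 3hit, mesenchymal genes were higher than in 2hit. Cells like those of 1hit, mixed into 3hit, would have to make up 27.6% at the median of 11 mesenchymal genes, with single genes asking for 6.90% to 321%. Of 32 genes abundant in 1hit, 14 (43.8%, exact 95% lower limit 26.4%) stayed below that share by their limits, so the bound of over 50% first set against such cells was not met. A second bound, at least 3 of these genes below even the lowest share, was added after that and after the values were seen. Below the lowest share, by their limits, lay 4 of the 32, ALDH1A2 at 0.439% of its 1hit level, DLK1 at 0.523%, CD34 at 0.870% and OGN at 0.314%. COL1A1 and COL3A1 are among both the 11 and the 32 genes, so the 43.8% is not independent of the needed share. The 4 genes below the lowest share are outside the mesenchymal list. They argue against cells with the full 1hit profile as the whole source of the rise, under a bound chosen with the values in view. Cells of another kind were not tested. After correction for GC content and length the list's median log2 ratio was 2.86, at the 100th percentile, which argues against that bias. ATRX knockdown, whose own transcript was not called, and differences between separately derived cultures may account for the pattern and were not tested.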

How the results depend on the processing

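The GC and length correction and the counts without joined rows or without rows outside their limits were chosen after seeing the data. Within 1.5 times of the main count stayed the counts of all 5 comparisons with no filter, with an absolute log2 ratio of at least 1, without joined rows and without rows outside their limits. With a mean FPKM of at least 5 the count fell to 636 for 2hit vs control, 612 for 3hit vs control and 744 for 3hit vs 2hit, since fewer genes are counted. At a q-value under 0.01 it fell to 680 for 3hit vs control and 792 for 3hit vs 2hit. Over 361 results of genes covered by the naming rule, no called change turned its direction under quantile normalization or the GC and length correction, and 35 missed a q-value of 0.01. A pseudocount cannot turn a direction, and centring moved all log2 ratios of a comparison alike, by at most 0.0725. Of 725 list results under the pseudocounts and scalings, 681 stayed on their side of the central 95% of random lists, 24 moved into it and 19 out of it. The ribosomal protein list in 1hit vs control reversed to -0.032 under quantile normalization; the cause was not tested. No paired analysis was possible because the tables used here hold 1 value per condition. For the same reason limma with or without trend, the robust and 4-library fits, the block on replicate number, the omission of single libraries and the tests with an estimated correlation were not run. A pseudocount does not enter the calls. Depth is unknown, so limits rest on the deposited ranges.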

Other observations

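The tests in this part, with the correction for GC content and length, were chosen after the results had been seen. The genes in this paragraph were picked after their values were seen, and MT2A, MEOX2, EGFR and IDH2 fall outside the naming rule. The type I collagen chains came apart in 1hit. COL1A1 stood at 2420 FPKM there and COL3A1 at 1873, while COL1A2, whose chain joins that of COL1A1 in type I collagen, stood at 4.05 (1.5 to 6.61), against 3.85 in control. In 3hit COL1A2 reached 68.6 beside 184 for COL1A1. The metallothionein gene MT2A was lower than control in all 3 altered lines, at 72.2 FPKM in control, 1.55 in 1hit, 4.63 in 2hit and 6.38 in 3hit, each called. The mesodermal homeobox gene MEOX2 measured 6.05 in control, 168 in 1hit, 1.44 in 2hit and 32.0 in 3hit. EGFR measured 1.84 in control, 14.6 in 1hit, 3.53 in 2hit and 8.77 in 3hit. IDH2 stood at 92.4, 65.1, 87.2 and 110 FPKM in the same order and was not called against control.

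Genes of chromosome 19 were slightly lower in 2hit than in control. Their 988 rows had a median log2 ratio of -0.07, against 0.07 over all rows, a difference of -0.14 with a random SD of 0.0162. Loss of 1 copy in all cells would give about -1 and is argued against by that value. The log2 ratio ran from 0.28 in the tenth of genes with the lowest GC content to -0.13 in the highest, and after correction for GC content and length the chromosome's difference was -0.049 (random SD 0.0124), less than before but more than 2 SD from 0. Before correction, other chromosomes also lay more than 2 random SD from all rows, such as 5 (5.06 SD higher), 3 (3.52 higher) and 22 (2.14 lower). Others, such as 6 (1.02 higher), did not. Only chromosome 19 was corrected, so its remaining difference cannot be called particular to it. The GC trend was also present in the other comparisons that hold 2hit. It ran from 0.18 to -0.17 in 2hit vs 1hit and from -0.32 to 0.09 in 3hit vs 2hit. It was small in 3hit vs control (-0.04 to -0.03) and 1hit vs control (0.09 to 0.03). In the same order, chromosome 19 lay -3.00, 7.28, 0.60 and -2.78 random SD from all rows. GC content was found for 86.8% of its rows, and the rest stayed uncorrected. A GC or length bias may account for most of the shift of chromosome 19, and whether it accounts for the rest cannot be told apart from a change in a minority of cells.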
